A study of Mus musculus with 6 samples.

How the data were processed

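Genomic DNA from 6 neocortex samples of mice at postnatal day 5 was assayed by RRBS, 3 labelled WT and 3 labelled Chd8+/- with replicate numbers 1 to 3 in each group. Per the labels' protocols, the DNA was digested with MspI, ligated to adapters, selected by fragment size, pooled and converted with bisulfite before PCR. The submitters' processing notes name Trim Galore 0.4.4, Bismark 0.20.0, SAMtools 1.9 and the genome build mm39. How these tools were set is not given in the sources used here, nor is whether reads were deduplicated. Molecular identifiers are not mentioned in the labels, so the spread expected from read counts covers counting error only.

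Each library came as a table of CpG cytosines with position, strand, coverage and the shares read as cytosine and as thymine. Coverage is a count of reads per cytosine, per the file headers. Sums of coverage, and shares of reads per chromosome, were taken over the listed CpG cytosines, so a read over several CpGs counts at each. The shares are deposited as percent, and the methylation level is the percent read as cytosine. The lowest coverage listed was 10 reads in each library. Coverage multiplied by the percent gave a whole number of methylated reads within 0.02 for over 99.9% of cytosines, and this number was rounded. The bisulfite conversion rate at cytosines outside CpGs was taken, as percent, from the authors' conversion statistics.

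The strands of each CpG were merged by adding reads. A CpG entered when its merged coverage was at least 10 reads in all 6 samples and it lay on an autosome. The level per sample was the unweighted mean over CpGs, compared between groups by an exact two-sided permutation test. Windows were fixed at 1000 bp from the start of each chromosome and needed at least 3 such CpGs. CpG density was the number of CpGs listed in any library within 250 bp on either side, the CpG itself included. This grouping replaced the planned compartments of promoter, exon, intron and intergenic DNA and was chosen after the data were seen. Classes by mean methylation level and by chromosome were also added after the data were seen.

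Differential methylation was tested on methylated and unmethylated read counts with edgeR 4.0.16 (quasi-likelihood test) in R 4.3.3, with a coverage term for each sample and the genotype acting on the methylated share. CpGs with a level of 0% or 100% in all 6 samples were left out. Calls were made at a Benjamini-Hochberg adjusted p under 0.05. Alternatives were logistic regression with an overdispersion factor, Fisher's exact test on pooled reads, limma 3.58.1 on log2 of the ratio of methylated plus 1 to unmethylated plus 1 reads, a coverage minimum of 20 reads, removal of CpGs above the 99.9th percentile of coverage, CpGs covered in at least 2 samples per group, windows of 500 and 2000 bp, chromosomes X and Y included, strands kept apart, an adjusted p of 0.1, a minimum difference of 10 points, reads as weights, the replicate number as a block, and each sample left out in turn. The limma fit, the class of the library by its share of reads on chromosome X (higher in replicate 3 of both groups) as a covariate and a limit of 1000 reads for the weighted mean were added after the data were seen. The edgeR, limma and logistic tests were tested on simulated counts for the real CpGs and windows. In these, 40 features were changed by each of 10, 20, 30, 40 and 60 points, drawn only from features with a mean level between 20% and 80%. The changed level was kept short of 0% and 100%, so some changes in the set of 60 points were smaller. The Fisher code was checked against scipy on random tables. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the other steps.

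The scatter between strands was expressed as the number of independent draws that would give the mean squared difference between the strands of a CpG in the same library, at intermediate methylation levels.

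The rule for named genes, fixed before the data were examined, was Chd8 first, then promoters, then the 5 CpGs and the 5 windows with the smallest p in each direction among those past the threshold, or otherwise the 3 with the smallest p, and then 2 members of each gene list. Only CpGs and windows could be named by it. The gene table at hand follows GRCm38 while the coordinates follow mm39, so promoters, gene bodies, imprinted promoters, promoter gene lists, annotated compartments and the CpGs of Chd8 were not analysed here, nor were their alternatives. A coverage minimum of 5 reads was not run because the tables list no cytosine below 10 reads. With Chd8 CpGs not analysed here, the genotype labels were not checked against the data.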

Results

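Neocortex from mice at postnatal day 5 was profiled by reduced representation bisulfite sequencing (RRBS), in which MspI cuts the genome at CCGG sites and bisulfite treatment turns unmethylated cytosines into uracil before sequencing. The design set 3 Chd8+/- samples, heterozygous for the chromatin remodeller gene Chd8, against 3 wild-type (WT) samples. The question was where CpG methylation of the neonatal neocortex differs when 1 copy of Chd8 is affected, a genotype used as a mouse model of the human neurodevelopmental disorder linked to CHD8. The labels do not say that the samples of a group came from separate animals, so the p-values measure the spread between these samples, part of which may be technical. Chromosome X held 2.58% and 2.56% of the summed coverage in replicate 3 of WT and Chd8+/-, against 1.18% to 1.21% in the other libraries. This argues against 1 animal behind all 3 samples of a group, but does not separate replicates 1 and 2.

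The WT libraries listed 1353412, 1400708 and 1199498 CpG cytosines with at least 10 reads, and the Chd8+/- libraries listed 1090948, 953724 and 1070146. Coverage summed over these cytosines was 49406794, 54818138 and 45498222 in WT and 39820333, 32285980 and 36887445 in Chd8+/-. In this sum a read over several CpGs counts at each. By it, every Chd8+/- library was shallower than every WT library. Median coverage per cytosine lay between 20 and 24 reads. A single cytosine on chromosome 2 at position 98496849 (mm39) took between 1.71% and 4.13% of this summed coverage. After the strands of each CpG were merged, 534921 autosomal CpGs had at least 10 reads in all 6 libraries, with a median coverage of 40 reads per library. These CpGs filled 69396 windows of 1000 bp, which held a median of 4 CpGs and 213 reads per library.

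At CpGs with 10 to 19 reads on each strand, the methylation levels of the 2 strands scattered as much as 2.94 to 3.13 independent draws per strand would give across the 6 libraries. At 40 to 79 reads per strand the scatter matched 7.78 to 10.5 draws.

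**Figure D1:**
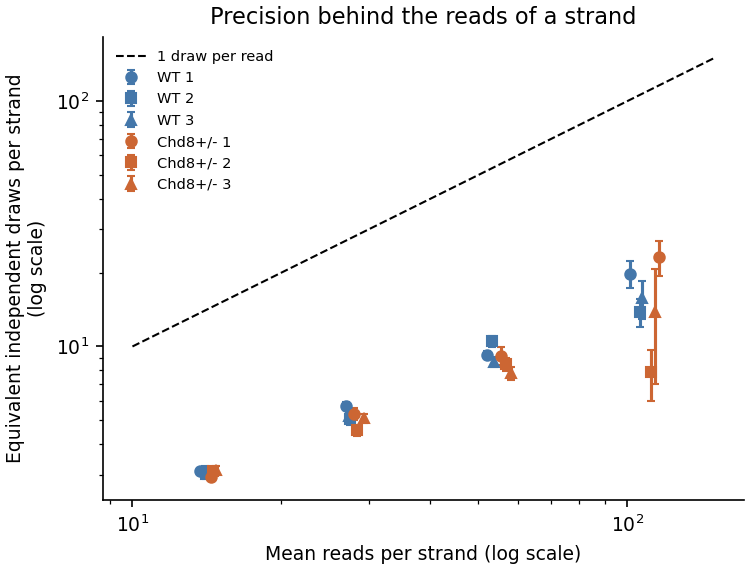
Precision of methylation levels at CpGs covered on both strands: the x axis gives the mean reads per strand and the y axis the number of independent draws that would give the observed scatter between strands, both on log scales. Each point is 1 library in 1 coverage class, bars are standard errors over chromosomes, and all points lie below the dashed line of 1 draw per read, with a mean of 3.07 draws at 10 to 19 reads and 8.97 at 40 to 79 reads.

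Autosomal CpG methylation averaged 47.7% ± 0.0247 (SD, n = 3) in WT and 48.3% ± 0.614 (SD, n = 3) in Chd8+/- neocortex. The Chd8+/- mean was 0.599 percentage points higher, with a standard error of 0.355. All 3 Chd8+/- samples, at 47.8%, 48.1% and 49.0%, lay above the highest WT sample, but Chd8+/- replicate 3 carried most of the difference. The exact two-sided permutation test gave p = 0.1, the smallest value that this test allows for 3 samples against 3. Without Chd8+/- replicate 3 the difference was 0.252 points. When CpGs were weighted by their reads it was 3.30 points, with group means of 48.7% ± 1.78 and 52.0% ± 2.55 (SD, n = 3) and an exact permutation p = 0.2. The weighted difference was 1.92 points without Chd8+/- replicate 3, and over CpGs of at most 1000 reads it was 2.74 points (exact permutation p = 0.3), with Chd8+/- replicate 1 at 47.2% below WT replicates 1 and 3 at 47.4% and 48.3%.

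The difference had the same sign on each of the 19 autosomes. It ranged from 0.478 points on chromosome 15 to 0.699 points on chromosome 4, and was 0.601 points on chromosome 14, the mouse chromosome that carries Chd8. Without Chd8+/- replicate 3 the differences ranged from 0.118 points on chromosome 15 to 0.352 points on chromosome 4, with 0.269 points on chromosome 14. The exact permutation p was 0.1 for 15 chromosomes and 0.2 for chromosomes 10, 13, 15 and 16, which gave Benjamini-Hochberg values of 0.127 and 0.2 over the family of 19.

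CpGs of intermediate methylation showed the widest gap between the groups. The classes were set by the mean level over the same 6 samples. This sorting can itself shift the shallower libraries within a class, so part of the pattern across classes may come from it. CpGs with a mean level of 20 to 40% stood at 28.7% ± 0.153 in WT and 30.9% ± 1.77 in Chd8+/- (SD, n = 3), a difference of 2.24 points over 29170 CpGs. Those at 40 to 60% differed by 2.13 points and those at 5 to 20% by 1.27 points. The 177867 CpGs under 5% differed by −0.0555 points, from 0.721% ± 0.0329 in WT to 0.666% ± 0.0437 in Chd8+/- (SD, n = 3). CpGs above 95% differed by 0.478 points and all 3 Chd8+/- samples were above all 3 WT samples there. In the class of 40 to 60%, Chd8+/- replicate 3 stood at 54.4%, the other Chd8+/- samples at 49.9% and 50.6%, and the WT mean at 49.5%. Over the family of 7 level classes the Benjamini-Hochberg values of the exact permutation tests ran from 0.175 to 0.8. Without Chd8+/- replicate 3 the differences were 1.26 points at 20 to 40%, 0.736 points at 40 to 60%, 0.134 in place of 0.462 points at 80 to 95%, and −0.0898 in place of 0.961 points at 60 to 80%.

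**Figure D2:**
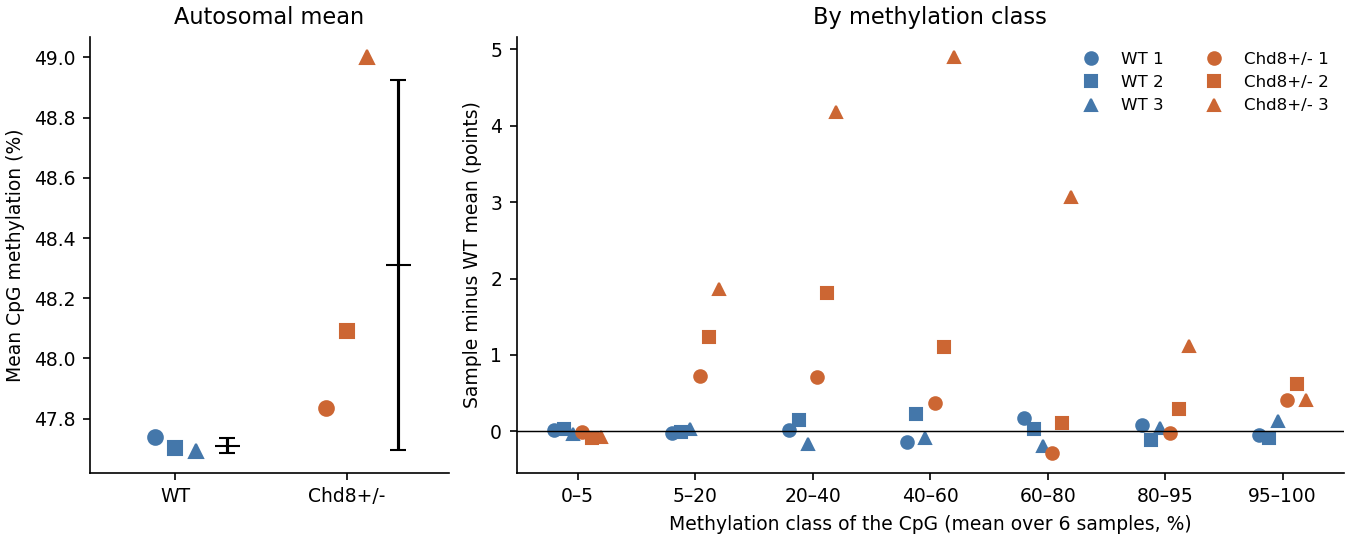
Left, mean methylation in percent over 534921 autosomal CpGs, with 1 point per sample and the mean ± SD of each group beside the points. Right, each sample minus the WT mean, in percentage points, by the mean level of the CpG, where Chd8+/- replicate 3 stands farthest above 0 from 5 to 95%.

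Methylation fell with CpG density in both genotypes. The sparsest CpGs, with 1 to 5 listed CpGs in the surrounding 500 bp, were methylated at 69.4% ± 0.0611 in WT and 70.2% ± 0.948 in Chd8+/- (SD, n = 3). Clusters of over 20 CpGs, the density typical of CpG islands, were nearly unmethylated at 2.02% ± 0.00557 in WT and 2.09% ± 0.0457 in Chd8+/- (SD, n = 3). The class of 6 to 10 listed CpGs stood at 53.6% and 54.3%, and that of 11 to 20 at 16.6% and 16.9%. The Chd8+/- samples were higher by 0.831, 0.690, 0.287 and 0.0645 points from the sparsest to the densest class. All 3 Chd8+/- samples exceeded all 3 WT samples in each of the 4 classes, and each exact permutation test gave p = 0.1, with a Benjamini-Hochberg value of 0.1. Without Chd8+/- replicate 3 the differences at the sparsest 2 classes were 0.293 and 0.336 points, and without Chd8+/- replicate 2 that of the densest class was 0.0390 points. At a minimum of 20 reads the densest class differed by 0.109 points, with Chd8+/- replicate 3 at 2.61% below WT replicate 3 at 2.63% and an exact permutation p of 0.2.

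Chromosome X separated replicate 3 of both genotypes from the other 4 libraries. In clusters of over 20 CpGs, X-linked CpGs were methylated at 34.9% in WT replicate 3 and 38.6% in Chd8+/- replicate 3, against 12.8% to 13.3% in the other 4 libraries. At 11 to 20 CpGs the levels were 35.3% and 39.3% against 13.9% to 14.7%. Chromosome X took 2.58% and 2.56% of the summed coverage in the replicate 3 libraries and 1.18% to 1.21% in the others. Between the 4 libraries with the lower X share, autosomal methylation was 0.242 points higher in Chd8+/- than in WT with 2 samples in each group, and between the pair with the higher share it was 1.31 points higher with 1 sample in each, which leaves no test. The labels give no sex. With chromosomes X and Y included, the mean difference between the genotypes was 0.598 points, but WT replicate 3 at 47.94% then lay above Chd8+/- replicate 1 at 47.93%, and the exact permutation p was 0.2.

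**Figure D3:**
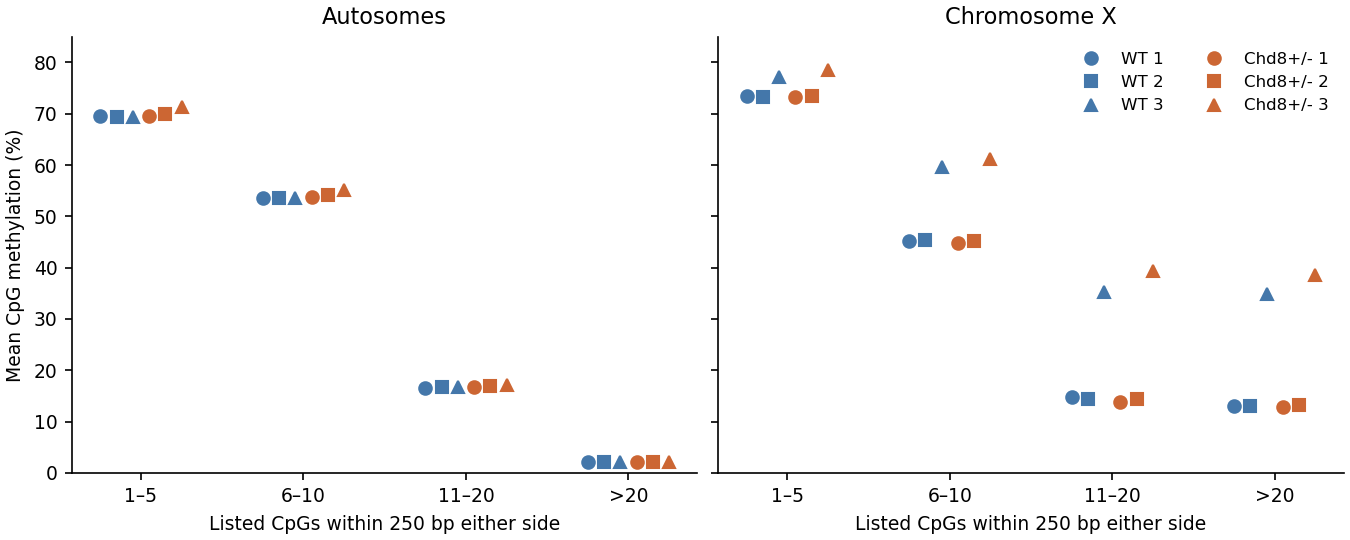
Mean CpG methylation in percent against the number of listed CpGs in the surrounding 500 bp, with 1 point per sample, on autosomes (left) and chromosome X (right). The autosomal points of the 6 samples lie close together in each class, while on chromosome X replicate 3 of both groups stands at 34.9% and 38.6% in the densest class.

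No individual CpG reached significance between the genotypes. With edgeR's quasi-likelihood test, 0 of 418119 CpGs and 0 of 68160 windows passed an adjusted p of 0.05, the lowest adjusted p being 0.765 for CpGs and 1.00 for windows. At an unadjusted p under 0.05 there were 15013 CpGs (3.59%) and 2566 windows (3.76%). Unchanged features simulated at the spread of these samples gave 3.78% of CpGs and 4.33% of windows, and the other 9 ways of grouping the samples gave 3.46% to 3.57% of CpGs and up to 3.81% of windows. Of those CpGs 8735 were higher and 6278 lower in Chd8+/- (58.2% higher, against 52.3% of all CpGs tested). Of those windows 1418 were higher and 1148 lower (55.3% higher), and across all windows tested 54.0% were higher. The median difference over all windows was 0.202 points, and without Chd8+/- replicate 3 these values were 51.3% and 0.0721 points. The logistic model with overdispersion and limma also called 0 CpGs and 0 windows, with 23394 and 21600 CpGs and 3382 and 3544 windows at an unadjusted p under 0.05. Fisher's exact test on pooled reads, which ignores the spread between samples, called 108187 CpGs and 22830 windows. When the samples were regrouped in the other 9 ways it called between 105167 and 106961 CpGs.

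The 3 windows with the smallest p lay on chromosomes 14, 11 and 3 (mm39). The window from 100048001 to 100049000 on chromosome 14, with 3 CpGs and 90 to 260 reads per sample, stood at 99.8% ± 0.301 in WT and 85.1% ± 6.18 in Chd8+/- (SD, n = 3). A window of 14 CpGs on chromosome 11 from 59730001 to 59731000 stood at 0.0650% ± 0.0571 in WT and 2.71% ± 1.33 in Chd8+/- (SD, n = 3, 547 to 1138 reads). On chromosome 3, the 10 CpGs from 116306001 to 116307000 stood at 1.34% ± 0.212 in WT and at 0 in all 3 Chd8+/- samples (394 to 1827 reads). In each of these windows all 3 samples of a group lay on the same side of the other group, and their adjusted p from edgeR was 1.00. The windows were picked by the smallest p in these same data, so this separation comes largely from the choice.

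The 3 CpGs with the smallest p were sparsely methylated sites with deep coverage. At position 104438832 of chromosome 12 methylation was 0 in all WT samples and 1.24% ± 0.292 in Chd8+/- (SD, n = 3). At position 91260324 of chromosome 9 it was 2.60% ± 0.663 in WT and 0 in Chd8+/-, and at position 38829684 of chromosome 12 it was 1.84% ± 0.329 in WT and 0 in Chd8+/- (SD, n = 3). Coverage ran from 319 to 525, 237 to 372 and 287 to 445 reads per sample at these sites, and each had an edgeR adjusted p of 0.765. Changes were simulated at the spread of these samples, only in features with a mean level between 20% and 80%. The reach of the test at sites as low as these 3 was therefore not simulated. In the set of 60 points 27 of 40 windows were called, and 0 of 40 at 10, 20, 30 or 40 points. Among single CpGs 7 of 40 were called in the set of 60 points, beside 3 unchanged CpGs called in error. At 40 points 97.5% of the changed windows and 62.5% of the changed CpGs had an unadjusted edgeR p under 0.05. The adjusted threshold also depends on how few features were changed among all those tested, which was not varied. On the same set of 60 points limma called 21 of 40 windows and 3 of 40 CpGs. The logistic model, run on the 66957 simulated windows and 398531 simulated CpGs with both methylated and unmethylated reads, called 0 of 40 and 0 of 40.

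**Figure D4:**
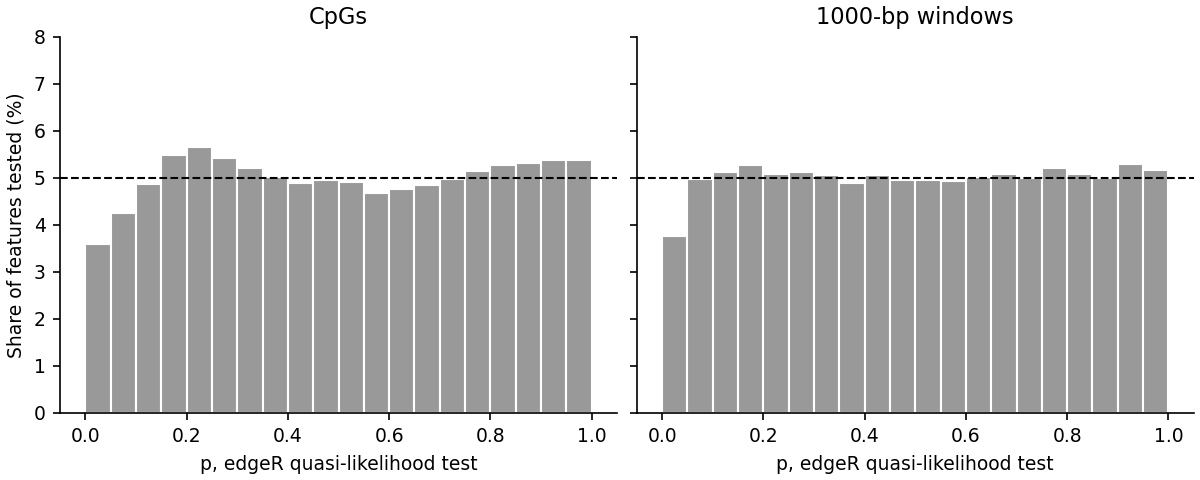
Distribution of unadjusted p from edgeR's quasi-likelihood test for CpGs (left) and windows of 1000 bp (right), Chd8+/- against WT. Bars give the share of features tested in percent, the dashed line marks the 5% per bar of a uniform distribution, and the lowest bar holds 3.59% of CpGs and 3.76% of windows.

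Methylation profiles were closely alike in the 6 samples. Across CpGs, which are not independent replicates, Pearson's r between libraries was 0.933 to 0.935 within WT, 0.918 to 0.923 within Chd8+/- and 0.922 to 0.930 between the genotypes. CpGs read as fully unmethylated or fully methylated made up 46.8% ± 1.37 of the total in WT and 51.4% ± 1.35 in the shallower Chd8+/- libraries (SD, n = 3, exact permutation p = 0.1).

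Bisulfite conversion at cytosines outside CpGs was nearly complete in both genotypes. The rate was 99.7% in each library, and the unconverted remainder was 0.319% ± 0.00291 in WT and 0.341% ± 0.0117 in Chd8+/- (SD, n = 3). The difference of 0.0218 points had an exact two-sided permutation p of 0.1. The 20 CpGs of the mitochondrial genome, read in all 6 libraries, stood between 0.355% and 0.510%.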

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

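The limma fit, the X-share class as covariate, the limit of 1000 reads, the weighted mean without Chd8+/- replicate 3, the X-share classes and the classes by density, chromosome and methylation level were chosen after the data were seen; the other alternatives were fixed before the data were examined. Of the main comparisons under their alternatives, 90 stayed on the same side of the threshold. This says little of stability, since no exact p could fall below 0.1 and a count of 0 has no direction. The other 2 moved: Fisher's exact test on pooled reads called 108187 CpGs and 22830 windows against 0 and 0, since it counts reads and not samples as replicates. Among the single sites, windows, chromosomes and level classes, 232 kept their direction. CpGs at 60 to 80% reversed to −0.0898 points without Chd8+/- replicate 3 (range over left-out samples −0.0898 to 1.58); no further cause was tested. The mean difference ranged from 0.252 to 0.837 points over left-out samples and was 0.642 points at 20 reads and 3.30 points weighted by reads. edgeR called 0 CpGs and 0 windows under each alternative, with lowest adjusted p of 0.0546 for CpGs (without Chd8+/- replicate 1) and 0.971 for windows.

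At autosomal CpGs, deviations from the group mean correlated at 0.00456, 0.000833 and 0.00233 between samples with the same replicate number. Between samples with different numbers the values ran from −0.00662 to 0.00421. Deviations of single CpGs carry counting error that can hide a shared effect, so these values cannot decide on pairing. The numbers were not taken as pairs in the main test. Both samples numbered 3 do stand apart together on chromosome X. With the replicate number as a block, edgeR called 0 CpGs and 0 windows, and the mean difference of 0.599 points had an exact paired p of 0.25, the smallest that 3 pairs allow. Promoter, gene body, imprinted and gene list alternatives and the minimum of 5 reads were not run. As to depth, CpGs with 10 to 19 reads per strand scattered like 3.07 independent draws per strand. Simulated changes of 40 points were called by edgeR at 0 of 40 CpGs and 0 of 40 windows. At an unadjusted edgeR p under 0.05 stood 62.5% of these CpGs and 97.5% of these windows. Depth, sample number and the number of features changed were not varied, so the 0 calls hold only for few changes among all features tested. They were made only at mean levels between 20% and 80%.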

Other observations

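The tests in this part were chosen after the result was seen, except that of coverage and the splits for CpGs and windows of 1000 bp.

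Over regions of 1 Mb the higher mean of the Chd8+/- group was spread widely, most of all in Chd8+/- replicate 3. Of 2084 regions with at least 50 CpGs, 1569 (75.3%) had a higher mean in Chd8+/-, and the share above the WT mean was 52.4%, 63.0% and 86.9% in Chd8+/- replicates 1, 2 and 3. By limma, 1 region was higher and 0 lower at an adjusted p under 0.05, with 163 regions at an unadjusted p under 0.05. It lay on chromosome 4 from 103000001 to 104000000 (mm39), where 144 CpGs stood at 51.8% ± 0.594 in WT and 56.5% ± 0.448 in Chd8+/- (SD, n = 3), with a limma adjusted p of 0.0442. After each sample was centred on its own mean, 0 regions passed and 133 had an unadjusted p under 0.05. Of the 10 splits of the 6 samples, 1 gave as many regions at the adjusted threshold, the real split, with 1 against 0 as the highest of the others. At an unadjusted limma p under 0.05 the others gave 63 to 144 regions, against 163 in the real split. For either count 10 splits are too few for a share under 0.05. For CpGs and windows of 1000 bp the real split gave 0 and 0 calls, and the highest of the others was 2 CpGs and 0 windows. That all 10 of 10 splits gave as many follows from a real count of 0, and the splits are again too few for a share under 0.05.

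The higher mean of the Chd8+/- samples was set against 3 technical explanations. Incomplete bisulfite conversion would raise unmethylated CpGs too. CpGs under 5% differed by −0.0555 points, but this class was set by the mean of the same 6 samples, so its sign cannot decide. Nearly unmethylated sites not sorted by level were higher in Chd8+/-, by values small against 0.599 points. These were 0.0645 for clusters of over 20 CpGs (0.109 at 20 reads) and 0.0218 for unconverted cytosines outside CpGs. Lower coverage at the single CpG is argued against by the 104240 CpGs where the mean coverage of the Chd8+/- libraries was equal or higher. Within these 6 samples the difference was 0.555 points there (standard error over chromosomes, not between samples, 0.0329) and 0.610 elsewhere. These CpGs come from the same libraries, so a property of the shallower libraries as a whole was not tested. PCR favouring methylated copies, which would act most in CpG-dense fragments, stays open: at intermediate levels the excess over the WT mean was larger in dense than in sparse sequence by a mean of 0.823 points in Chd8+/-, from −0.246 in replicate 3 to 1.73 in replicate 2, while WT samples ran from −0.572 to 0.815. Both groups held 1 library with the higher X share, the mean was higher in Chd8+/- within either class (by 0.242 and 1.31 points), and a genotype effect, a different mix of cells and litter stay open and untested, with 0.252 points left without Chd8+/- replicate 3.

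The scatter between strands of one CpG may come from PCR copies of few template molecules. The number of equivalent draws rose 2.92 times from 10 to 19 reads to 40 to 79 reads, as it would if molecules and reads both grow with the yield of a fragment. Methylation that truly differs between strands would recur in other libraries, but the highest correlation of the strand difference between 2 libraries was 0.0654 over 20658 CpGs. A hypothesis that follows is that reads overstate the precision of single CpGs in all 6 libraries. No biological explanation tied to the groups was tested for this scatter.

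The methylation of CpG-dense X-linked DNA in replicate 3 of both groups could come from 1 active and 1 inactive X chromosome. The share of summed coverage on chromosome X in these libraries was 2.15 times that of the other 4 libraries. The replicate 3 libraries listed 209 and 194 Y cytosines against 1024 to 1357. With the X share, this argues against the same sex chromosomes in replicate 3 as in the other 4 libraries. Their share of summed coverage on chromosome Y was only slightly lower, at 0.0912% and 0.0801% against 0.101% to 0.143%. This Y coverage therefore lay on fewer and deeper cytosines. Whether these reads came from chromosome Y or from similar sequence elsewhere was not tested. A gain of this size at CpG-dense DNA across the whole library is argued against, since autosomal CpGs of the same density differed by −0.0267 points between the replicate 3 libraries and the other 4. That class is nearly unmethylated, so it does not speak to a gain at other CpGs. Over all autosomal CpGs Chd8+/- replicate 3 stood at 49.0% and WT replicate 3 at 47.7%. Dense X-linked CpGs were higher in Chd8+/- replicate 3 than in WT replicate 3, at 38.6% and 34.9%, a comparison of 1 sample with 1 that has no replicate check. The other 4 libraries showed no such gap, at 13.1% and 13.0% in WT and 12.8% and 13.3% in Chd8+/-. Whether the gap between the replicate 3 libraries belongs to the genotype or to the higher autosomal level of Chd8+/- replicate 3 was not tested.

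Among sequences outside the main comparison, the unplaced contig MU069435v1 held 130 CpGs at 30.4% to 35.0% in WT and 32.4% to 36.1% in Chd8+/-. The contig JH584304v1 held 42 CpGs at 56.0% to 61.9% in WT and 60.4% to 64.2% in Chd8+/-. On chromosome Y, 130 CpGs were read in all 6 libraries, and Chd8+/- replicate 2 stood at 78.6% against 88.1% to 90.9% in the other 5. The replicate 3 libraries are among these, and whether the 130 CpGs are specific to chromosome Y was not tested.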
